A study of Homo sapiens with 6 samples.

How the data were processed

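RNA from Raji cells, a human Burkitt lymphoma line, was measured after 24 h with 100 nM JQ1 or with DMSO, 3 arrays each, on Affymetrix Human Gene 1.0 ST arrays. Per the submitters' processing notes the intensities were made by the authors with RMA, a method of background correction, quantile normalization and median polish. Its software version and any filter on probe sets are not given in the sources used here. As deposited, the intensity values are linear, not log2: they run from 4.00 to 21822 with medians of 76.0, 76.4 and 74.9 for DMSO and 75.8, 76.1 and 79.9 for JQ1. The plan had assumed log2 values and provided for taking log2 of a linear file, which was done. The series matrix and the authors' processed table hold identical values for 28000 probe sets. That table also holds log2 fold changes of JQ1 over DMSO made by the authors, close but not equal to differences of mean log2 values, and adjusted p-values from the authors, whose test and adjustment are not given in the sources used here. The authors' mean intensities per group in the same table are arithmetic means of 3 linear values.

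Probe sets were named from the platform's probe table. It gives 1 gene symbol for 19014 probe sets, several for 1374 and none for 7612; 18984 of those with 1 symbol matched a gene ID. Of several transcript clusters for 1 gene, as for 556 genes, the one with the highest mean over the 6 arrays stood for the gene, which left 18356 genes. A name in a fixed list that is a current symbol of an unmeasured gene was not matched through synonyms. The deposited table named 1178 probe sets that the platform table does not, and genes measured by these alone entered in an added alternative only. Genes of the mitochondrial genome, a list with 0 of 13 members measured, were not tested. The result for 1 gene fixed by name is not reported here.

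JQ1 was compared with DMSO in limma 3.58.1 under R 4.3.3 (lmFit and eBayes on log2 values, two-sided, no filter on signal, prior degrees of freedom 4.68), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Fixed lists, 33 with at least 3 members measured, were tested with camera at a preset correlation of 0.01, with camera at a correlation estimated per list, and with fry, adjusted over the lists. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Before the data were examined, the groups, the test, the lists, the alternatives and the rule for named genes were fixed. The rule named the 12 genes that rose most and the 12 that fell most among those past the threshold, with groups that did not overlap and a mean in the higher group at or above the median of all genes. It passed over LOC, open reading frame, microRNA, small nucleolar and pseudogene entries and immunoglobulin and T cell receptor segments. It also named genes fixed by name and, in each list, up to 4 members with the smallest p among those past the threshold, or up to 2 where none passed. Of the 120 genes so named some belong to more than 1 list.

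Precision was tested on simulated data with known shifts: over 5 rounds 56.4% of genes shifted by 0.5 (log2), 94.3% of those shifted by 1 and 96.7% of those shifted by 1.5 were called, and 5.29% of all calls were unshifted genes. In the simulation genes and arrays varied independently and few genes were shifted. Real genes and same-numbered arrays vary together, so these shares need not hold for the real arrays. The numbers 1 to 3 in the labels were checked for pairing. Over 9178 genes at or above the median level, deviations from the group mean correlated at 0.477, 0.248 and 0.455 between DMSO and JQ1 arrays of the same number, and at -0.431 to -0.0315 between other numbers. The replicate number was therefore also fitted as a block, as an alternative fixed beforehand.

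The other alternatives were filters on signal at the median (log2 6.91) and the 25th percentile (5.27), a second quantile normalization, centring on array medians, the values of the processed table, the mean of all transcript clusters, eBayes with trend and robust, array quality weights, thresholds of 0.01 and of a 1.5-fold change, and leaving out each array in turn. Using the names of the deposited table as well was chosen after seeing the data.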

Results

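Raji is a human B cell line from a Burkitt lymphoma, a tumour driven by deregulated MYC. JQ1 is a small molecule that binds the bromodomains of the BET proteins and displaces them from acetylated chromatin. Cells were exposed for 24 h to 100 nM JQ1 or to DMSO, its solvent. RNA of 3 samples per treatment was measured on 6 Affymetrix Human Gene 1.0 ST arrays, whose probes lie along the whole length of each transcript. The median deposited intensity of an array lay between 74.9 and 79.9. The comparison asked which transcripts differed in level between JQ1 and DMSO. A change is the JQ1 mean minus the DMSO mean of log2 RMA values, given with its standard error (SE) from limma, with 3 arrays per group throughout. A gene rose or fell where its Benjamini-Hochberg adjusted p was under 0.05.

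Among the 12 genes that rose most after JQ1, CD69, an early activation antigen, rose 4.20-fold (log2 change 2.07, SE 0.52, adjusted p = 0.0329). BCL2A1, an anti-apoptotic relative of BCL2, rose 4.08-fold (2.03, SE 0.44, adjusted p = 0.0194). The cytokine genes TNF (1.89, SE 0.32) and LTA (1.86, SE 0.45) rose with NFKBIA (1.60, SE 0.29), which encodes an inhibitor of NF-kB. CD83, a surface antigen of activated lymphocytes, rose by 1.36 (SE 0.32). Also among the 12 were the histone genes H2BC12 (1.68, SE 0.21) and H3C10 (1.30, SE 0.29), and ANO6, a lipid scramblase of the membrane (1.44, SE 0.17). TAGAP, a gene of activated T cells (1.34, SE 0.096), TXNIP, which binds thioredoxin (1.29, SE 0.17), and TCP11L2, a little-studied gene (1.24, SE 0.13), completed the 12. Each of the 12 lay higher on all 3 JQ1 arrays than on any DMSO array, as the rule that named them required. Their adjusted p ran from 0.00131 for TAGAP to 0.0329 for CD69.

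For 5 of these genes the call ended when 1 of several arrays was left out, although the rise remained. Without each array in turn the change was 1.48 to 2.47 for CD69, 1.69 to 2.54 for BCL2A1 and 1.39 to 2.44 for LTA. It was 1.08 to 1.77 for CD83 and 0.94 to 1.55 for H3C10. The call, in contrast, depended on which array was left out. It ended for CD69 without DMSO replicate 2 or 3 or JQ1 replicate 3, and for LTA without any array but JQ1 replicate 1. It ended for BCL2A1 and CD83 without DMSO replicate 1 or 2 or JQ1 replicate 2 or 3, and for H3C10 without JQ1 replicate 2 or 3. The highest adjusted p among these was 0.107, for LTA. With an intensity trend and robust variances the same 5 missed the threshold, at 0.114 for CD69, 0.0778 for BCL2A1, 0.104 for LTA, 0.0961 for CD83 and 0.0713 for H3C10. Over all alternatives their adjusted p ran from 0.000397 to 0.114.

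Of the 12 genes that fell most, 5 belong to the DNA replication list. CDC6, which loads the replicative helicase, fell by 1.95 (SE 0.26), and DTL, a ubiquitin ligase adaptor of S phase, fell by 1.87 (SE 0.22). The replication factors MCM10 (-1.71, SE 0.24), POLE2 (-1.65, SE 0.21) and CDC45 (-1.62, SE 0.22) fell too. Outside that list stood CDC25A, a phosphatase that activates CDK2 (-1.62, SE 0.20). SPARCL1, a gene for a secreted matrix protein, fell 4.12-fold (-2.04, SE 0.32, adjusted p = 0.00634). MYB, a transcription factor of haematopoietic progenitors, fell 4.01-fold (-2.00, SE 0.18, adjusted p = 0.00151). SMAD1, which transmits BMP signals (-1.98, SE 0.21), and SLC38A5, a glutamine transporter (-1.94, SE 0.14), fell by similar amounts. ACKR4, a scavenging chemokine receptor (-1.94, SE 0.22), and FAM111B, a protease gene (-1.73, SE 0.21), completed this group. Each of the 12 was lower on all 3 JQ1 arrays than on any DMSO array, again as the rule required. Their adjusted p ran from 0.00131 for SLC38A5 to 0.00634 for SPARCL1. All 12 calls were kept whichever array was left out.

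**Figure D1:**
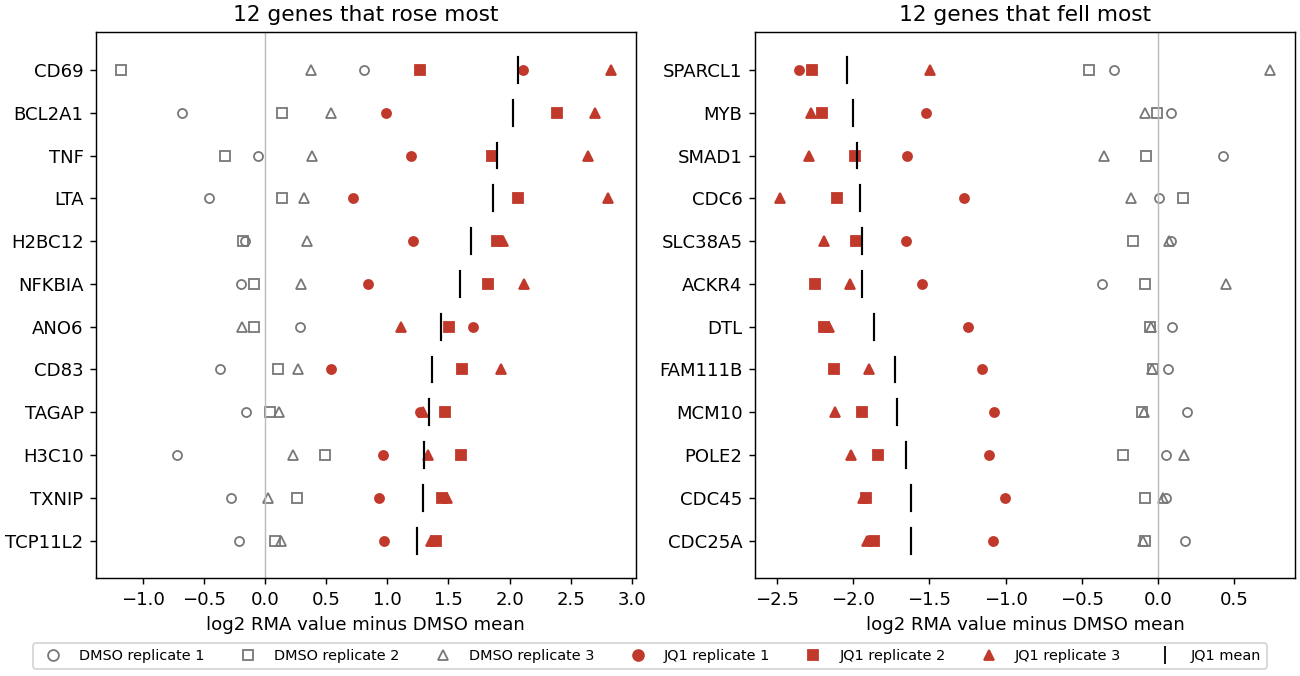
Each point is one array's log2 RMA value minus the mean of the 3 DMSO arrays (horizontal axis) for the 12 genes that rose most (left) and the 12 that fell most (right), with open grey symbols for DMSO, filled red symbols for JQ1, shapes for the replicate number and a black tick at the JQ1 mean. The means run from 1.24 for TCP11L2 to 2.07 for CD69 on the left and from -2.04 for SPARCL1 to -1.62 for CDC25A on the right. By the rule that named these genes, no JQ1 point overlaps the DMSO points of its gene.

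In all, 915 of 18356 genes rose and 1417 fell, together 2332 or 12.7%, and 4775 had an unadjusted p under 0.05. Of the changed genes 166 differed at least 2-fold, 23 higher and 143 lower. The groups did not overlap for 5922 genes (32.3%), where chance gives 10%. An exact permutation test of 1 gene on 3 against 3 arrays could not reach a two-sided p below 0.10, so only limma, which pools variances across genes, was used for single genes. These p-values measure only the spread between these samples, and the labels do not say whether the samples were separate cultures. The quantile normalization in RMA gives the probe intensities of all arrays a common distribution, so a change in the total RNA per cell would not show. The resulting values per probe set need not share one, and their array medians ran from 74.9 to 79.9. The number of changed genes was 1008 (347 rose, 661 fell) without DMSO replicate 1, 1047 (383 and 664) without DMSO replicate 2 and 1352 (530 and 822) without DMSO replicate 3. It was 1011 (342 and 669) without JQ1 replicate 2 and 1555 (624 and 931) without JQ1 replicate 3.

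The authors' deposited table gives 3423 of the same genes an adjusted p under 0.05. Of these, 1442 were among the 2332 genes called here, all 1442 with the same sign. Across genes, which are not independent replicates, the authors' log2 fold changes and those computed here correlated at r = 0.985. Both were made from the same deposited values, so the shared signs and this correlation are no independent support.

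Among the genes fixed by name, HEXIM1, whose product holds the elongation kinase P-TEFb inactive, rose 2.15-fold (1.10, SE 0.13, adjusted p = 0.00283). MYC, the oncogene translocated in Burkitt lymphoma, stood at a log2 level of 11.20 with DMSO (SD 0.079) and 11.28 with JQ1 (SD 0.12). Its difference of 0.08 (SE 0.085, adjusted p = 0.614) was no larger than the spread between replicates. The BET genes BRD2 (0.21, SE 0.083, adjusted p = 0.139) and BRD3 (-0.08, SE 0.074, adjusted p = 0.585) did not pass the threshold. SERPINI1, a neuronal serpin gene used as a marker of BET inhibition, rose 1.39-fold (0.47, SE 0.12, adjusted p = 0.0402) from a low log2 level of 4.74. Its call ended without any array but JQ1 replicate 1, and at 0.0587 when the arrays were quantile-normalized again. Over the alternatives its adjusted p ran from 0.0120 to 0.125.

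DNA replication genes formed the most uniform group: all 43 fell, and all 43 fell adjusted over the list alone. The number that fell was 34 without DMSO replicate 1, 35 without DMSO replicate 2 and 39 without DMSO replicate 3. It was 43 without JQ1 replicate 1, 33 without JQ1 replicate 2 and 38 without JQ1 replicate 3. Each time all 43 fell at an unadjusted p under 0.05 in limma. The median change of the list was -1.06 (camera adjusted p = 1.01e-32, adjusted p = 0.516 with an estimated correlation). MCM5, a subunit of the replicative helicase, fell by 1.60 (SE 0.17), CCNE2, the S phase cyclin E2, fell by 1.40 (SE 0.15) and RFC2, a clamp loader subunit, fell by 1.05 (SE 0.12). Among mitosis genes 25 of 32 fell, or all 32 adjusted over the list alone, with a median of -0.79 (camera adjusted p = 6.29e-17, adjusted p = 0.516 with an estimated correlation). FOXM1, a transcription factor of mitotic genes (-1.11, SE 0.20), CDC25C, a phosphatase of mitotic entry (-0.97, SE 0.18), and the kinases AURKA (-0.94, SE 0.13) and CDK1 (-0.90, SE 0.16) were among them. Of 22 nucleotide synthesis genes 14 fell, or 18 adjusted over the list alone, with a median of -0.37 (camera adjusted p = 3.71e-09, adjusted p = 0.516 with an estimated correlation). They included the ribonucleotide reductase genes RRM2 (-1.01, SE 0.20) and RRM1 (-0.81, SE 0.15), the purine enzyme PFAS (-0.59, SE 0.083) and the folate enzyme MTHFD1 (-0.58, SE 0.097).

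These were 3 of the 13 lists, out of 33 tested, that moved against the other genes with camera at its preset correlation of 0.01. With an estimated correlation camera called 0 lists, with 1 at an unadjusted p under 0.05. The rotation test fry, which does not set a list against other genes, called 10 lists in one direction and 30 in either direction. In one direction fry did not call mitosis (adjusted p = 0.0784), ribosome biogenesis (0.105), glycolysis (0.0784) or histone clusters (0.114). Nor did it call immediate early genes (0.114) or NF-kB targets (0.149), although camera at its preset correlation called all of these. On single arrays the median of the DNA replication genes against the DMSO mean was -0.63 for JQ1 replicate 1, -1.30 for JQ1 replicate 2 and -1.35 for JQ1 replicate 3. The number of mitosis genes that fell was 5 without DMSO replicate 1 or 2 or JQ1 replicate 2, 9 without DMSO replicate 3 and 11 without JQ1 replicate 3. For nucleotide synthesis it was 3 without DMSO replicate 1 or JQ1 replicate 2, 4 without DMSO replicate 2, 6 without DMSO replicate 3 and 7 without JQ1 replicate 3. RRM2 lost its call without DMSO replicate 1 or 2 or JQ1 replicate 2, with adjusted p from 6.81e-05 to 0.0598 over its alternatives.

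**Figure D2:**
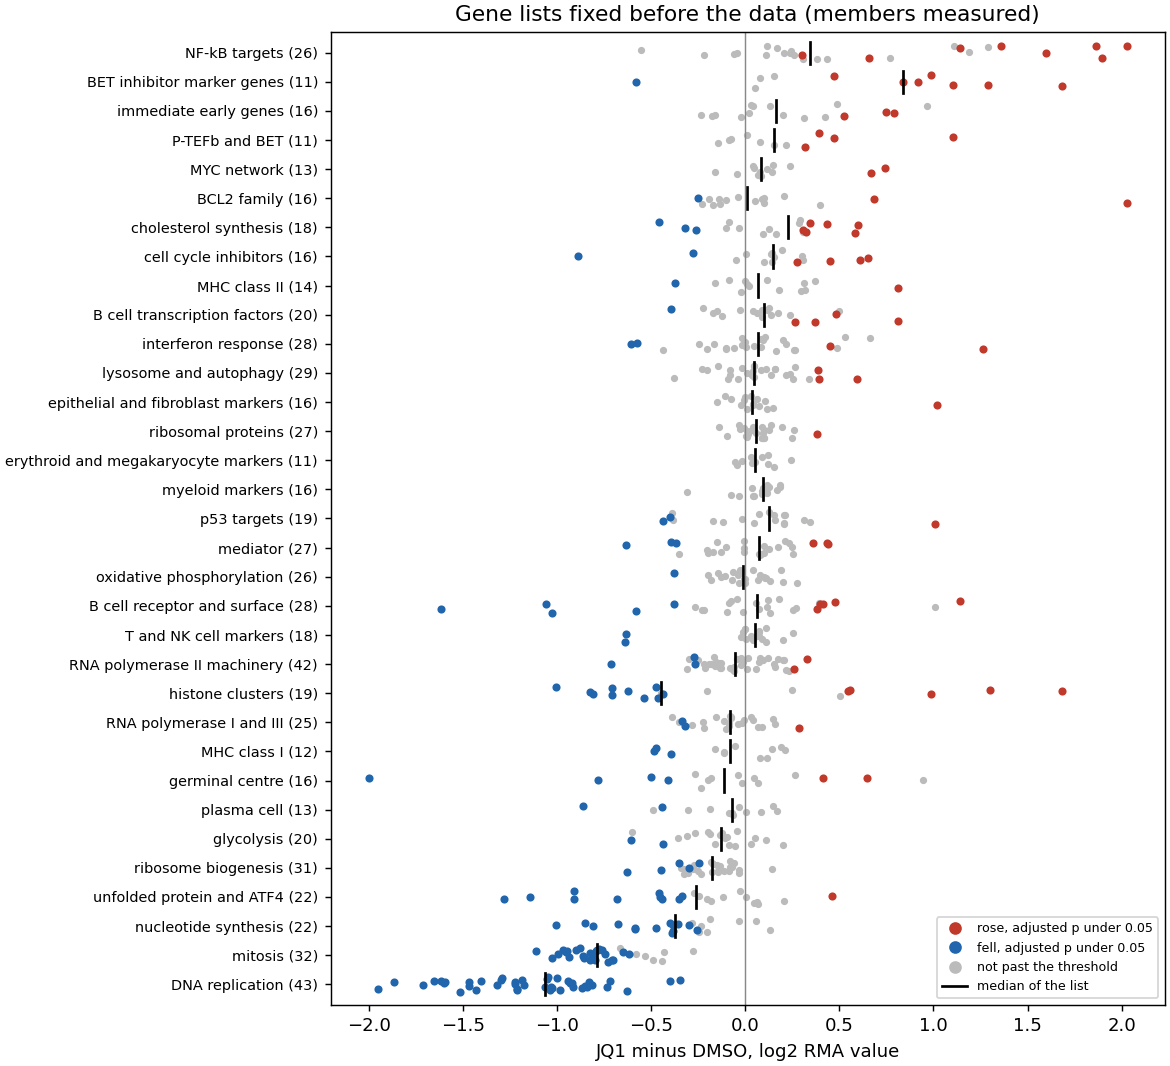
Each point is the JQ1 minus DMSO change in log2 RMA value (horizontal axis) of one member of a gene list (vertical axis, ordered by the mean of the list), red where it rose, blue where it fell and grey where it did not pass the adjusted p threshold, with a black bar at the median. The median is -1.06 for DNA replication and -0.79 for mitosis, against 0.34 for the NF-kB targets and 0.84 for the BET inhibitor marker genes.

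Genes chosen as markers of BET inhibition were higher as a list: 7 of 11 rose and 1 fell, the same numbers adjusted over the list alone. The list had a median of 0.84 (camera adjusted p = 8.47e-05, adjusted p = 0.516 with an estimated correlation). It set no direction for each marker, so its median and test do not score a marker response. DCXR, a carbonyl reductase gene, rose by 0.92 (SE 0.078) beside HEXIM1, H2BC12 and TXNIP. CD180, a toll-like receptor homologue of B cells, fell by 0.58 (SE 0.096). Without DMSO replicate 1 the number that rose was 4. In the list of P-TEFb and BET genes 4 of 11 rose, also adjusted over the list alone, with a median of 0.15 (camera adjusted p = 0.0325, adjusted p = 0.516 with an estimated correlation). Beside HEXIM1 these were AFF1 (0.47, SE 0.090) and AFF4 (0.39, SE 0.069), scaffolds of elongation complexes, and CCNT1, the cyclin of P-TEFb (0.32, SE 0.075). Without JQ1 replicate 1 the call on this list ended (adjusted p = 0.0616, from 0.00906 to 0.516 over the alternatives). CCNT1 lost its call without any array but JQ1 replicate 1, with adjusted p from 0.0107 to 0.101 over its alternatives.

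In the MYC network 2 of 13 genes rose, also adjusted over the list alone, with a median of 0.08 (camera adjusted p = 0.0371, adjusted p = 0.516 with an estimated correlation). They were MXD4 (0.74, SE 0.083) and MXD1 (0.67, SE 0.10), whose products compete with MYC for their partner MAX. The call on the list ended without DMSO replicate 1 (0.0941), JQ1 replicate 1 (0.0616) or JQ1 replicate 2 (0.0599). It also ended with filters on signal at the 25th percentile (0.0525) and at the median (0.0908), from 0.00839 to 0.516 over the alternatives.

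NF-kB targets were higher as a group: 8 of 26 rose, and adjusted over the list alone 14 rose and 1 fell. As a list they had a median of 0.34 (camera adjusted p = 7.81e-05, adjusted p = 0.530 with an estimated correlation), and TNF, NFKBIA, BCL2A1 and CD83 had the smallest p among them. With fry in one direction the list did not pass (adjusted p = 0.149). Against the DMSO mean the median of the list was 0.14 on JQ1 replicate 1, 0.54 on JQ1 replicate 2 and 0.91 on JQ1 replicate 3, while DMSO replicate 3 stood at 0.21. The number that rose was 2 without DMSO replicate 1 or 2 or JQ1 replicate 2 or 3, 5 without DMSO replicate 3 and 15 without JQ1 replicate 1.

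Of 16 immediate early genes 3 rose, or 4 adjusted over the list alone, with a median of 0.16 (camera adjusted p = 0.0267, adjusted p = 0.530 with an estimated correlation). These were JUN (0.79, SE 0.092) and JUND (0.52, SE 0.081), both subunits of AP-1, and DUSP2, a phosphatase that acts on MAP kinases (0.75, SE 0.16). The call on the list ended without DMSO replicate 2 (0.0992) or JQ1 replicate 1 (0.0517), with array weights (0.0686) and with a filter at the median signal (0.0597), from 0.00300 to 0.530 over the alternatives. DUSP2 lost its call without DMSO replicate 1 or 2 or JQ1 replicate 2 (from 0.00219 to 0.0719 over its alternatives), and 5 genes of the list rose without JQ1 replicate 1. The BCL2 family did not move as a list (camera adjusted p = 0.839), with 2 of 16 higher and 1 lower, also adjusted over the list alone. BCL2A1 and MCL1, another anti-apoptotic gene (0.68, SE 0.11, adjusted p = 0.00634), rose, and the pro-apoptotic BAD fell by 0.25 (SE 0.069, adjusted p = 0.0467). BAD lost its call without each single array and with the replicate block (0.0591, from 0.0182 to 0.149 over its alternatives). The number of BCL2 family genes that rose was 1 without DMSO replicate 1 or 2 or JQ1 replicate 2 or 3.

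**Figure D3:**
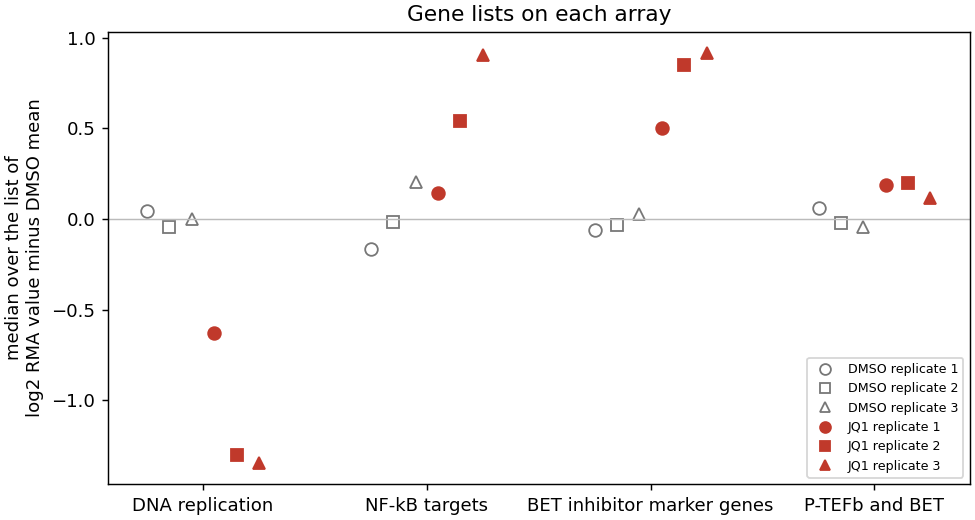
Each point is the median over one gene list (horizontal axis) of an array's log2 RMA value minus the mean of the 3 DMSO arrays (vertical axis), with open grey symbols for DMSO, filled red symbols for JQ1 and shapes for the replicate number. For DNA replication JQ1 replicate 1 lies at -0.63 against -1.30 and -1.35 on the other JQ1 arrays, whereas for P-TEFb and BET the JQ1 arrays lie between 0.11 and 0.20.

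Ribosome biogenesis genes were slightly lower as a group: 5 of 31 fell, or 10 adjusted over the list alone. The median over the list was -0.18 (camera adjusted p = 1.95e-06, adjusted p = 0.530 with an estimated correlation). LYAR, a nucleolar protein of growing cells, fell by 0.63 (SE 0.11, adjusted p = 0.0103). The nucleolar genes GAR1 (-0.45, SE 0.12), NOP16 (-0.36, SE 0.080) and MYBBP1A (-0.30, SE 0.070) fell too. Without any array but JQ1 replicate 1 these 3 lost their calls and the number that fell was 1, with adjusted p for the 3 from 0.0106 to 0.142 over the alternatives. GAR1 also lost its call when the arrays were quantile-normalized again (0.0536) or centred on their medians (0.0518).

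Genes of RNA polymerases I and III did not pass as a list (camera adjusted p = 0.0856): of 25, 1 rose and 2 fell, or 1 and 4 adjusted over the list alone. POLR1D, a shared subunit, rose by 0.29 (SE 0.069), while POLR3G, a polymerase III subunit, fell by 0.34 (SE 0.091) and TAF1A, of a polymerase I initiation factor, fell by 0.32 (SE 0.086). Without any array but JQ1 replicate 1 no member passed in limma, with 1 higher and 5 or 6 lower at an unadjusted p under 0.05, and without JQ1 replicate 1 the number that fell was 4. The RNA polymerase II machinery did not move as a list (camera adjusted p = 0.202), with 2 of 42 higher and 3 lower, also adjusted over the list alone. SSRP1, a subunit of the histone chaperone FACT, fell by 0.71 (SE 0.11, adjusted p = 0.00627), and the initiation factor gene GTF2H4 (-0.27, SE 0.068) and the shared subunit gene POLR2F (-0.27, SE 0.073) fell too. CDC73, of the PAF1 elongation complex, rose by 0.33 (SE 0.078). Without any DMSO array or JQ1 replicate 2 the number of these genes that rose was 0 in limma, with 3 or 4 at an unadjusted p under 0.05, and without JQ1 replicate 1 it was 1. The number that fell was 1 without any array but JQ1 replicate 1. Calls on TAF1A, GTF2H4 and POLR2F ended without each single array, and CDC73 lost its call without any DMSO array or JQ1 replicate 2, with adjusted p from 0.00969 to 0.137 over the alternatives. With the replicate block TAF1A (0.0665) and POLR2F (0.0537) missed the threshold.

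Among 27 mediator genes, whose products link transcription factors to polymerase II, 3 rose and 3 fell, or 7 and 3 adjusted over the list alone (camera adjusted p = 0.645). MED11 (0.44, SE 0.067), MED19 (0.43, SE 0.080) and MED23 (0.36, SE 0.072) rose, and MED24 fell by 0.63 (SE 0.11). MED19 lost its call without DMSO replicate 1 and MED23 without DMSO replicate 1 or 2 or JQ1 replicate 2, with adjusted p from 0.00505 to 0.0658 over the alternatives. Without any array but JQ1 replicate 1 the number of mediator genes that fell was 1, and without DMSO replicate 1 the number that rose was 1.

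Genes of the unfolded protein and amino acid responses were lower as a list: 10 of 22 fell and 1 rose, or 12 and 1 adjusted over the list alone. Their median change was -0.26 (camera adjusted p = 2.17e-05, adjusted p = 0.516 with an estimated correlation). SDF2L1, of an endoplasmic reticulum chaperone complex, fell by 1.15 (SE 0.15), and PSAT1, a serine synthesis enzyme, fell by 0.91 (SE 0.13). SLC7A11, the cystine transporter, fell by 0.68 (SE 0.088) and PDIA6, a disulfide isomerase, fell by 0.46 (SE 0.072). The number that rose was 0 in limma without DMSO replicate 2 or 3 or JQ1 replicate 2 or 3, with 1 or 2 at an unadjusted p under 0.05, and 7 to 11 fell without each single array. Of 20 glycolysis genes 2 fell, or 4 adjusted over the list alone, with a median of -0.13 (camera adjusted p = 0.00527, adjusted p = 0.530 with an estimated correlation). These were the hexokinase gene HK2 (-0.61, SE 0.14, adjusted p = 0.0216) and the phosphofructokinase gene PFKP (-0.44, SE 0.082, adjusted p = 0.0116). Neither passed in limma without DMSO replicate 1 or 2, where 5 and 4 genes of the list fell at an unadjusted p under 0.05, and HK2 also lost its call without JQ1 replicate 2 or 3, with adjusted p from 0.00409 to 0.0885 over the alternatives.

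Cholesterol synthesis did not pass as a list (camera adjusted p = 0.0593), although 6 of 18 genes rose and 3 fell, or 8 and 3 adjusted over the list alone. The sterol reductase gene TM7SF2 (0.60, SE 0.095), the cyclase gene LSS (0.58, SE 0.12) and the isomerase gene IDI1 (0.43, SE 0.072) rose, and EBP, a sterol isomerase, fell by 0.46 (SE 0.080). With the replicate block the list passed (adjusted p = 0.0403), as it did without DMSO replicate 3 (0.0396) or JQ1 replicate 1 (0.0233). Rescaled arrays (0.0312 and 0.0427) and array weights (0.0357) also brought it under the threshold, from 0.0233 to 0.530 over the alternatives. The number that rose was 2 without DMSO replicate 1 or 2 or JQ1 replicate 2 and 3 without DMSO replicate 3 or JQ1 replicate 3, and without each single array 1 fell. LSS lost its call without DMSO replicate 1 or 2 or JQ1 replicate 2 (from 0.00134 to 0.0686 over its alternatives).

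Lysosome and autophagy genes did not pass as a list with camera (adjusted p = 0.121; fry in one direction, adjusted p = 0.0460), with 3 of 29 higher, also adjusted over the list alone. These were the sialidase gene NEU1 (0.59, SE 0.074), the proton pump subunit ATP6V1A (0.39, SE 0.069) and the saposin precursor PSAP (0.39, SE 0.088). The list passed when the arrays were quantile-normalized again (0.0252, from 0.0252 to 0.530 over the alternatives), and 5 genes rose and 1 fell without JQ1 replicate 1. PSAP lost its call without DMSO replicate 2 or 3 or JQ1 replicate 2 or 3 (from 0.0101 to 0.0950 over its alternatives). Of 26 oxidative phosphorylation genes (camera adjusted p = 0.751) CYC1, cytochrome c1, fell by 0.38 (SE 0.088). Of 27 ribosomal protein genes (camera adjusted p = 0.0975) RPS29, of the small subunit, rose by 0.38 (SE 0.094), and neither gene passed adjusted over the list alone. Without DMSO replicate 1 or 2 or JQ1 replicate 2 or 3 neither was called, and RPS29 also lost its call without JQ1 replicate 1, with adjusted p from 0.0107 to 0.114 over the alternatives.

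Histone genes of the replication-dependent clusters moved in both directions: 5 of 19 rose and 10 fell, or 5 and 12 adjusted over the list alone. Their median change was -0.45 and their mean -0.08 (camera adjusted p = 0.0396, lower; adjusted p = 0.530 with an estimated correlation). H2BC12, H3C10 and the linked H2B gene H2BC11 (0.55, SE 0.092) rose, while H2AC16, an H2A gene (-0.81, SE 0.12), and H3C2, an H3 gene (-0.62, SE 0.11), fell. With the replicate block the list missed the threshold (adjusted p = 0.0702), as it did without DMSO replicate 2 (0.0773), DMSO replicate 3 (0.102), JQ1 replicate 2 (0.0599) or JQ1 replicate 3 (0.0621). Filters on signal at the 25th percentile (0.0872) and the median (0.282) also ended the call, from 0.0138 to 0.530 over the alternatives. The number that fell was 3 without DMSO replicate 1 or JQ1 replicate 2 and 6 without DMSO replicate 2 or 3 or JQ1 replicate 3. The number that rose was 3 without DMSO replicate 1 or 2 and 2 without JQ1 replicate 2 or 3.

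Inhibitors of the cell cycle were higher as a list: 4 of 16 rose and 2 fell, or 6 and 2 adjusted over the list alone. Their median change was 0.15 (camera adjusted p = 0.0245, adjusted p = 0.516 with an estimated correlation). The growth arrest genes GADD45B (0.65, SE 0.11) and GADD45A (0.45, SE 0.072) and the antiproliferative BTG1 (0.61, SE 0.088) rose. RBL1, which encodes the pocket protein p107, fell by 0.89 (SE 0.17). In a grouping by symbol made after the data were seen, 10 genes are named CDKN, the CDK inhibitors of the list among them. Of the 10, 0 rose and 2 fell, with a median of -0.0017. The call on the list ended without DMSO replicate 1 (0.0637) and with filters at the 25th percentile (0.0533) and the median (0.0559), from 0.00642 to 0.516 over the alternatives. The number that fell was 0 in limma without DMSO replicate 1 or 2 or JQ1 replicate 2, with 2 at an unadjusted p under 0.05, and 1 without DMSO replicate 3 or JQ1 replicate 1.

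The p53 targets did not pass as a list (camera adjusted p = 0.608): of 19, 1 rose and 2 fell, or 1 and 3 adjusted over the list alone. TP53INP1, a stress response gene, rose by 1.01 (SE 0.18), while MDM2, the ubiquitin ligase of p53, fell by 0.40 (SE 0.065) and AEN, an apoptotic nuclease, fell by 0.44 (SE 0.096). RBL1 lost its call without DMSO replicate 1 or 2 or JQ1 replicate 2, and AEN without any DMSO array or JQ1 replicate 2, with adjusted p from 0.000411 to 0.0824 over the alternatives. The number of p53 targets that fell was 1 without any DMSO array or JQ1 replicate 2 and 4 without JQ1 replicate 1, and 2 rose without DMSO replicate 3 or JQ1 replicate 1.

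Lists of B cell identity did not pass with camera, although single genes changed. Of 20 B cell transcription factors 4 rose and 1 fell, or 5 and 2 adjusted over the list alone (camera adjusted p = 0.111; fry in one direction, adjusted p = 0.0377). SPIB, an ETS factor of B cells, rose by 0.81 (SE 0.12), IRF8, an interferon regulatory factor, by 0.48 (SE 0.087) and POU2F2, which encodes OCT2, by 0.37 (SE 0.084). TCF3, which encodes E2A, fell by 0.39 (SE 0.10). TCF3 lost its call without any array but JQ1 replicate 1 and POU2F2 without DMSO replicate 1 or 2 or JQ1 replicate 2 or 3, with adjusted p from 0.00453 to 0.130 over the alternatives. Without DMSO replicate 1 or 2 or JQ1 replicate 2 or 3 the number of factors that rose was 2.

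Among 28 genes of the B cell receptor and surface 5 rose and 5 fell, or 7 and 6 adjusted over the list alone (camera adjusted p = 0.831, with a median of 0.06 and a mean of -0.01). TNFRSF17, the BCMA receptor, fell by 1.62 (SE 0.15, adjusted p = 0.00180) to a log2 level of 4.43, below the 25th percentile of all genes (5.27). CD72, an inhibitory coreceptor, fell by 1.03 (SE 0.13) and CD38, an ectoenzyme, rose by 0.40 (SE 0.069). The number that rose was 1 without DMSO replicate 1 or 2 or JQ1 replicate 2, 3 without JQ1 replicate 3 and 9 without JQ1 replicate 1, and 3 fell without DMSO replicate 2 or 3. In the germinal centre list 2 of 16 rose and 4 fell, or 3 and 5 adjusted over the list alone (camera adjusted p = 0.133; fry in one direction, adjusted p = 0.0232). MYB, the AKT coactivator gene TCL1A (-0.79, SE 0.12) and MYBL1, a MYB relative (-0.50, SE 0.073), fell, and ELL3, an elongation factor, rose by 0.41 (SE 0.078). Of 13 plasma cell genes 2 fell, or 3 adjusted over the list alone: FKBP11 (-0.86, SE 0.083) and MZB1 (-0.44, SE 0.092), both of the secretory pathway. That list missed the threshold (camera adjusted p = 0.0694) and passed it without DMSO replicate 2 (0.0369) or JQ1 replicate 3 (0.0339), from 0.0339 to 0.530 over the alternatives. ELL3 lost its call without DMSO replicate 1 or JQ1 replicate 2 and MZB1 without DMSO replicate 1 or 2 or JQ1 replicate 2, with adjusted p from 0.00378 to 0.0726 over the alternatives. Germinal centre genes that rose numbered 0 in limma without DMSO replicate 1 or JQ1 replicate 2, with 2 and 3 at an unadjusted p under 0.05, and 1 without DMSO replicate 2 or JQ1 replicate 3.

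Interferon response genes did not pass as a list (camera adjusted p = 0.627): of 28, 2 rose and 2 fell, or 3 and 2 adjusted over the list alone. The antiviral genes IFIT2 (1.26, SE 0.19, from a log2 level of 4.91 below the 25th percentile) and OAS1 (0.45, SE 0.087) rose, while IFIT5, which binds viral RNA (-0.57, SE 0.084), and XAF1, an antagonist of XIAP (-0.61, SE 0.15), fell. OAS1 lost its call without DMSO replicate 1 or 2 and XAF1 without any DMSO array or JQ1 replicate 3, with adjusted p from 0.00371 to 0.101 over the alternatives. The number of interferon response genes that rose was 6 without JQ1 replicate 1.

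Of 14 MHC class II genes 1 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.289). HLA-DQB1, a class II beta chain, rose by 0.81 (SE 0.19), and RFXAP, a regulator of the class, fell by 0.38 (SE 0.087). Of 12 MHC class I genes 3 fell, also adjusted over the list alone (camera adjusted p = 0.289). They were the peptide-trimming ERAP2 (-0.47, SE 0.10) and ERAP1 (-0.39, SE 0.069) and the immunoproteasome subunit PSMB8 (-0.48, SE 0.084). Calls ended for RFXAP without any array but JQ1 replicate 1, for HLA-DQB1 without any DMSO array or JQ1 replicate 3 and for ERAP2 without DMSO replicate 2 or 3 or JQ1 replicate 2 or 3. Array weights also ended the call of HLA-DQB1 (0.0577), and adjusted p for these 3 ran from 0.00629 to 0.104 over the alternatives. Without JQ1 replicate 1 the number of class II genes that rose was 4.

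Lists of markers of other cell types did not pass with camera. The median log2 level was 5.47 for T and NK cell markers, 5.32 for myeloid, 5.39 for erythroid and megakaryocyte and 5.68 for epithelial and fibroblast markers, against 6.91 for all genes, with 1, 1, 0 and 3 members above that level. In the same order the camera adjusted p was 0.839, 0.222, 0.404 and 0.448. Of 18 T and NK cell markers 2 fell, also adjusted over the list alone: LCK, a kinase that some B cell tumours express (-0.64, SE 0.079), and CD247, a T cell receptor chain (-0.63, SE 0.094). The median of that list was 0.05 and its mean -0.01, and 1 member rose without JQ1 replicate 1. Of 16 epithelial and fibroblast markers ACTA2, a smooth muscle actin, rose by 1.02 (SE 0.082, adjusted p = 0.00147) from a log2 level of 7.79, also adjusted over the list alone. No myeloid or erythroid marker passed in limma, with 0 of 16 and 1 of 11 at an unadjusted p under 0.05. Smallest p belonged to the scavenger receptor gene CD163 (0.18, SE 0.089, adjusted p = 0.235) and the granule enzyme MPO (0.18, SE 0.092, adjusted p = 0.253) in the first list. In the other they belonged to the platelet gene GP9 (0.24, SE 0.072, adjusted p = 0.0619) and the globin gene HBB (0.15, SE 0.097, adjusted p = 0.368). GP9 passed with a filter on signal (0.0407) and when the arrays were quantile-normalized again (0.0475), from 0.0407 to 0.169 over its alternatives.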

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

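The tests on JQ1 replicate 1 were chosen only after the result was seen, as was the count of probe sets outside the gene test; the count over other splits was planned.

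Probe sets that name several genes or none carried changes too, and were counted because the main comparison does not use them, though some entered the alternative with added names. In a limma fit over all 28000 probe sets, 1953 (6.975%) changed. Among the 8986 probe sets that name several genes or none the share was lower, at 299 (3.33%). Of these 156 were higher and 143 lower, and 1303 of the 8986 had an unadjusted p under 0.05. Those naming several genes held 104 of the 299 (of 1374), those with no gene symbol 192 (of 7592), and those matched to the mitochondrial genome record 3, all higher (of 20, with a median change of 0.31). The total was 82 without DMSO replicate 1, 56 without DMSO replicate 2, 91 without DMSO replicate 3, 343 without JQ1 replicate 1, 51 without JQ1 replicate 2 and 122 without JQ1 replicate 3. No explanation was tested for these.

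JQ1 replicate 1 lay closer to DMSO than the other JQ1 arrays: on the first principal component (61.3% of the variance) it stood at 6.18, against 19.6 and 26.6 for the other JQ1 arrays and -19.2 to -16.3 for DMSO. DMSO RNA mixed into this sample would give genes that rose and genes that fell the same DMSO share. The medians were 68.9% (95% bootstrap interval 53.4 to 79.3, 48 genes) and 40.0% (37.2 to 43.4, 244 genes), 28.9 percentage points apart. The bootstrap draws genes as if independent, but genes move together (estimated correlation 0.843 in the DNA replication list and 0.594 in the NF-kB list). The intervals in this paragraph are therefore too narrow, and the gap, on 1 array, goes only weakly against mixing as the whole cause. A difference shared with DMSO replicate 1 came to 8.33% (5.82 to 10.2) of the shortfall of 0.67 for the genes that fell. For the genes that rose it came to 46.1% (33.2 to 72.3) of 0.69, where it stays open, as same-numbered arrays also correlated at 0.477. Both sets of genes came from a fit that included DMSO replicate 1, which favours genes with little spread among the DMSO arrays. The first value therefore argues only within that limit against a shared difference for the genes that fell. The BET inhibitor marker genes stood at 0.50 on JQ1 replicate 1 against 0.85 and 0.92 on the other JQ1 arrays, whereas the P-TEFb and BET genes stood at 0.19 against 0.20 and 0.11. Whether the sample responded less stays open, and no biological explanation was tested.

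Of the 10 ways to split the 6 arrays into 3 and 3, 1 gave as many changed genes as the real one, namely the real split itself, with 2332. The highest of the other splits was 0 in limma, with 265 to 968 genes at an unadjusted p under 0.05 against 4775. Of those, 3 parted the 3 same-numbered pairs as the real split does, with 434, 265 and 428 such genes. With 10 splits the share cannot be under 0.05. Each of the other splits also mixes JQ1 and DMSO arrays within its groups, so the difference between treatments widens the spread within them. Their low counts are thus in part fixed by the design and do not show what like groups would give.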

How the results depend on the processing

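Using the deposited names as well was chosen after seeing the data; all other alternatives here were planned. No named gene changed its direction under any alternative, and no list past the threshold did. The camera test reversed for 4 lists not past the threshold under any alternative, and the cause was not tested. These were oxidative phosphorylation with the filter at the median signal (mean -0.00614) and with a second quantile normalization (0.0244), T and NK cell markers with the filter at the 25th percentile (-0.0666) and with a second quantile normalization (-0.0302), and lists with single arrays left out. The B cell receptor and surface reversed without DMSO replicate 1, JQ1 replicate 2 or JQ1 replicate 3 (means without each array from -0.0999 to 0.111), the interferon response without DMSO replicate 1 or JQ1 replicate 2 (0.0247 to 0.188) and T and NK cell markers without DMSO replicate 1 or JQ1 replicate 3 (-0.0333 to 0.00987). The mean of the mediator list, not past the threshold either, changed sign without JQ1 replicate 1 and with the filter at the median signal. The number of changed genes moved from 2332 (915 higher, 1417 lower) to 730 (244 and 486) at an adjusted p under 0.01 and to 749 (172 and 577) with a fold of at least 1.5, where stricter thresholds admit fewer genes. Array quality weights gave 3194, with 1386 higher; the cause was not tested. Leaving out each array gave 1008 to 2668 changed genes, 342 to 1013 higher and 661 to 1655 lower, the lowest total without DMSO replicate 1 and the highest without JQ1 replicate 1, and here fewer arrays enter each fit. The other alternatives gave 2163 to 2700. Among them, a second quantile normalization made the directions more even, with 1156 higher and 1307 lower (46.9% higher, against 39.2% in the main fit). The replicate block gave 2626 genes (2183 shared with the 2332), and it ended the calls on TAF1A (0.0665, from 0.0215 to 0.137 over its alternatives), POLR2F (0.0537, from 0.0179 to 0.136), BAD (0.0591, from 0.0182 to 0.149) and the histone list (0.0702, from 0.0138 to 0.530), brought the cholesterol list under the threshold (0.0403, from 0.0233 to 0.530) and changed no other call on a named gene or list. Of the 113 named genes past the threshold, 75 kept their call without any single array and 38 lost it without at least 1: 34 without DMSO replicate 1, 35 without DMSO replicate 2, 21 without DMSO replicate 3, 5 without JQ1 replicate 1, 32 without JQ1 replicate 2 and 26 without JQ1 replicate 3. Trend and robust variances ended 5 calls on named genes, a second quantile normalization 6, centring 5 and array weights 1. The second quantile normalization ended those on SERPINI1, GAR1, TAF1A, GTF2H4, POLR2F and BAD. Centring ended those on GAR1, POLR3G, TAF1A, POLR2F and BAD. Of the 13 lists past the threshold, 0 kept their call in camera with an estimated correlation (1 list at an unadjusted p under 0.05), 4 lost it with the filter at the median signal and 3 with that at the 25th percentile. With the filter at the median, 16 of the 120 named genes and 3 lists had no value. The values of the deposited processed table, the mean of all transcript clusters and the added names changed no call on a named gene or list. Background signal was not analysed here; in the lowest of 5 equal bins of level 33 genes rose and 28 fell, against 331 and 461 in the highest.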

Other observations

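All families and tests in this part were chosen only after the result was seen, except the tests of host genes and of signal level. Several families defined by their symbols moved after JQ1, among 244 with at least 10 members. Nucleoporins, which build the nuclear pore, were lower: 11 of 23 fell, with a median of -0.27 (camera adjusted p = 1.53e-06, adjusted p = 0.968 with an estimated correlation, as for the 3 families that follow), among them NUP85 (-0.80, SE 0.12), NUP205 (-0.58, SE 0.11) and NUP155 (-0.51, SE 0.090). Of 16 genes named RAD, many of them for DNA repair, 10 fell, with a median of -0.38 (camera adjusted p = 0.000124), such as RAD51AP1, a recombination factor (-1.40, SE 0.24), and RAD54L, a recombination helicase (-1.33, SE 0.17). Centrosomal CEP genes were lower (11 of 37 fell and 1 rose, median -0.25, camera adjusted p = 0.000522), with CEP55, which acts in the last step of cell division, at -1.06 (SE 0.22) and CEP41 at -0.98 (SE 0.073). In the other direction, 6 of 16 TRAPPC genes, which serve vesicle tethering, rose, with a median of 0.23 (camera adjusted p = 0.00366), among them TRAPPC6A (0.48, SE 0.11) and TRAPPC11 (0.39, SE 0.072). The named members were chosen after their values were seen.

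All 4 medians kept their sign when the arrays were rescaled. Without DMSO replicate 1, DMSO replicate 2, DMSO replicate 3, JQ1 replicate 2 and JQ1 replicate 3 in turn, the nucleoporins that fell numbered 3, 4, 6, 5 and 6, the RAD genes 5, 6, 5, 5 and 5 and the CEP genes 4, 3, 4, 4 and 8. The TRAPPC genes that rose numbered 1 without DMSO replicate 1 or 2, 3 without JQ1 replicate 2 and 4 without DMSO replicate 3 or JQ1 replicate 3. Without JQ1 replicate 1 the counts were 12, 10, 16 and 7.

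Over all 55 replication-dependent histone genes measured, 5 rose and 25 fell. Without DMSO replicate 1 the counts were 3 and 11, without DMSO replicate 2 they were 3 and 14, without JQ1 replicate 2 they were 2 and 13 and without JQ1 replicate 3 they were 2 and 19. Signal shared between near-identical copies would make genes of 1 type move alike, yet 4 of the 16 H2B genes rose and 5 fell (2 and 3 without DMSO replicate 1, 2 and 4 without DMSO replicate 2, JQ1 replicate 2 or JQ1 replicate 3), which argues against it as the whole cause. A candidate explanation is that copies known to give polyadenylated transcripts escape the fall of the others. The 9 such copies measured had a median of 0.50 (4 rose, 2 fell) and the other 46 a median of -0.46 (1 rose, 23 fell), with a two-sided permutation p of 0.00013 (100000 permutations). The copies were listed after the values were seen and their genes are not independent, so this p decides nothing and the explanation stays open.

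Of 115 box C/D small nucleolar RNAs, which guide methylation of ribosomal RNA, 21 rose and 0 fell in limma (33 and 3 at an unadjusted p under 0.05), with a median of 0.14 (camera adjusted p = 0.000545, adjusted p = 0.968 with an estimated correlation); 10 rose without DMSO replicate 1 or JQ1 replicate 3, 12 without DMSO replicate 2, 11 without DMSO replicate 3 and 13 without JQ1 replicate 2, while without JQ1 replicate 1 22 rose and 3 fell. A drift with signal level is argued against, since 10000 random lists of the same levels had medians from -0.03 to 0.04 (95% range), against 0.145. Higher transcription of the host genes was tested by host RNA level, for the 35 RNAs with an enclosing gene measured. The 25 enclosing genes had a median of 0.0332 (95% bootstrap interval -0.0507 to 0.0641), the RNAs 0.16. For these 35 RNAs this argues, within limits, against a rise in host RNA level as the whole cause. The interval draws genes as if independent and may be too narrow. Enclosing genes were found by position without regard to strand, so some may not be hosts. Across these RNAs, which are not independent replicates, the changes of RNA and host correlated at 0.376. Transcription itself was not measured and RNA level cannot stand for it, so higher transcription of the hosts stays open. A higher share of all small RNAs would raise every class, but of 3 other classes 1 lay above its random range, the spliceosomal RNAs (0.41), while H/ACA RNAs (0.03) and microRNAs (0.03) lay within theirs; a rise shared by some classes stays open. Of 61 H/ACA RNAs 6 rose and 0 fell in limma (12 and 1 at an unadjusted p under 0.05); 1 rose without DMSO replicate 1, DMSO replicate 3 or JQ1 replicate 3 and 0 without DMSO replicate 2 or JQ1 replicate 2 (7 and 10 at an unadjusted p). Of 19 spliceosomal RNAs 2 rose, and 0 in limma without DMSO replicate 2, JQ1 replicate 2 or JQ1 replicate 3 (4, 9 and 4 at an unadjusted p). No biological explanation was tested.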
